A study of Caenorhabditis elegans with 6 samples.

How the data were processed

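RNA pulled down with 3xFLAG-tagged ADR-1 was measured in 3 CLIP libraries and 3 size-matched input libraries from whole mixed-stage C. elegans grown at 20 °C. No library of an untagged strain or a mock pulldown was among them. CLIP over input therefore cannot separate RNA in contact with ADR-1 from RNA held by the beads. Per the labels' protocols, animals were crosslinked at 3 J/cm2, lysates of 5 mg were treated with 150 units of RNase I, 2% of each lysate was kept as input, and the rest was immunoprecipitated with anti-FLAG beads and passed through an on-bead ligation step meant for RNA duplexes. Whether the replicates came from separate cultures is not given in the sources used here, so p-values measure the spread between these libraries, which can be technical.

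Reads were trimmed and mapped with fastp 0.21.0 and STAR 2.7.10b against ce11 or WBcel235, per the submitters' processing notes. Clusters were called with CLIPPER and annotated with a WormBase release, per the file captions. The authors deposited raw read counts per cluster and library, in a list of 736 reproducible clusters and in a list of 636 uniquely annotated ones, in which all 636 clusters had the same coordinates and counts. No deposited count was 0 and the lowest over all libraries was 1, so a count of 0 may stand as 1. Of the 636 clusters, 241 had an input count of 1 in all 3 inputs. The p-value deposited per cluster and replicate came from a chi-square or Fisher test, per the file captions. The deposited log2 fold was found to be the log2 ratio of CLIP reads plus 1 over input reads plus 1, without scaling for library size, in 736 of 736 clusters of each replicate. A further deposited log2 column was found to be the log2 ratio scaled for library totals. The deposited chi-square score was found to be the Yates-corrected statistic of reads inside and outside a cluster. Coordinates are printed as deposited, and whether they count from 0 or 1 is not given in the sources used here.

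Library totals were recovered by fitting that statistic to the deposited scores. The fit met 130 of 130, 73 of 76 and 116 of 116 scores within rounding. The recovered CLIP totals had standard errors of 0.0345%, 1.06% and 0.0911%, and that of replicate 3 over replicate 1 was 1.000 within an error of 0.000974. The recovery was tested on simulated scores with known totals. Library-scaled log2 ratios were computed from the counts and these totals, and lay within 0.000498 of the deposited ones.

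CLIP was compared with input by edgeR 4.0.16 (glmQLFit and glmQLFTest, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05), with no replicate block. TMM scaling had been written down before the data were examined. It was replaced as the main setting by the recovered library totals after the files were seen, because the tables hold only clusters chosen for enrichment and TMM sets their median to 0; the TMM values are given beside the main ones. The biological coefficient of variation was 0.672. On 736 simulated clusters, the test called 84.0% of those with a log2 fold of 4, 24.0% of those with 2, 2.00% of those with 1 and 0.933% of unchanged ones. Simulated counts were drawn around each cluster's mean over all libraries, CLIP and input together. They had a common dispersion, no floor on counts and no filter, unlike the real data and the main fit. The call rates therefore do not carry over to the real clusters, whose inputs were mostly far lower than their CLIP counts. DESeq2 1.42.0 and limma 3.58.1 (camera, over the cluster classes) were run in R 4.3.3, and the remaining tests in Python 3.11 with scipy. Same-numbered CLIP and input libraries come from a common lysate per the labels' protocols. Their deviations from the group means had correlations of 0.332, 0.113 and 0.00162 over clusters.

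Gene names were taken from the files, where 315 are given; 301 matched a RefSeq symbol of WBcel235 and 14 matched through the locus tag. tRNA clusters carry identifiers only. Cluster classes are the authors' annotation. For the 100 other clusters, a tRNA or non-coding RNA on the same strand took precedence, then a 3' UTR, then an intron. Gene lists (16, from ADAR substrates to tissue markers) were written before the data were examined, except that genes of the mitochondrial genome were matched by chromosome after the names in the list matched no symbol. Lists and arms were tested with two-sided Fisher's exact tests, adjusted over lists, against genes with reproducible clusters outside the uniquely annotated list. A gene counted in that background if such a cluster named it on the same strand, also where the cluster lay in its intron.

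The genes named are the 20 with the largest deposited fold of a cluster averaged over replicates, the 10 with the most clusters, every bound member of the ADAR substrate and RNA machinery lists, and up to 4 members of each other list; values are those of the cluster with the largest fold. Alternatives were scaling (TMM, DESeq2 size factors), no filter, the replicate block, each library left out, stricter cluster lists, other class orders, other backgrounds, a matched permutation of 100000 draws and other limits of the arms. Analyses of inverted repeats and of predicted folding were planned and not run, as no genome sequence was used here.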

Results

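ADR-1 is a member of the ADAR family of double-stranded RNA binding proteins of Caenorhabditis elegans. It lacks deaminase activity of its own and is known to affect where the active enzyme ADR-2 edits adenosines. Binding was mapped by CLIP in whole mixed-stage animals of a strain carrying a 3xFLAG tag on ADR-1. In CLIP, RNA is crosslinked to protein by ultraviolet light, trimmed with RNase, pulled down with the tagged protein and sequenced. The data comprised 3 CLIP libraries and 3 size-matched input libraries, numbered 1 to 3, and the question was which RNAs, and which parts of them, ADR-1 contacts in the animal. Read counts were given for 736 clusters found reproducibly, of which 636 were listed as uniquely annotated and significant and give 363 gene identifiers. Genes with a cluster among the 636 are called bound below. Without an untagged control, the word does not separate contact with ADR-1 from RNA held by the beads.

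The library totals behind the deposited statistics came to 5776766, 5770295 and 5775877 reads for CLIP replicates 1, 2 and 3, and to 4159015, 2474074 and 4248635 for the inputs. Clusters held 161579, 33129 and 93381 CLIP reads, or 2.80% (95% Wilson interval 2.78 to 2.81), 0.574% (0.568 to 0.580) and 1.62% (1.61 to 1.63) of these totals. They held 7161, 2305 and 7208 input reads, or 0.172% (0.168 to 0.176), 0.0932% (0.0894 to 0.0970) and 0.170% (0.166 to 0.174). The median cluster had 74, 17 and 43 CLIP reads and 1 input read in each replicate, so at the median cluster the input count limits the precision of the fold. The 3 CLIP totals were equal within error, and whether each is the library's own depth is not known, which bears on the CLIP shares and on every scaled ratio. Totals set by the median cluster, which assume equal enrichment, would be 1118360 for CLIP replicate 2 and 3211680 for replicate 3. The intervals cover counting error only.

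By the deposited fold, which is not scaled for library totals, the highest of the 636 uniquely annotated clusters lay in the 3' UTR of zig-11 (WBGene00021305, chromosome V, 1875747 to 1875808, minus strand), an immunoglobulin-domain gene, with 1516, 214 and 904 CLIP reads against 2, 1 and 1 input reads. Its library-scaled log2 ratio was 8.33 ± 1.57 (SD, n = 3), with an edgeR adjusted p of 2.58e-07. The 3' UTR of C50D2.7 (WBGene00016810, chromosome II, 92318 to 92439) came next in deposited fold, with a library-scaled log2 ratio of 7.62 ± 1.27, and then that of sao-1 (WBGene00011195, chromosome V, 13965248 to 13965352) with 7.17 ± 1.54 (SD, n = 3). All 3 replicates lay above 0 on this log2 scale for each of these 3 clusters. Across the 20 genes with the largest deposited fold, 19 had this cluster in a 3' UTR, and the exception was the non-coding RNA Y81B9A.5 on chromosome X at 6.35 ± 2.05 (SD, n = 3).

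Other genes among these 20 included uba-2 (WBGene00006700), a subunit of the SUMO-activating enzyme, at 7.55 ± 2.34, and epg-3 (WBGene00012559), an autophagy gene, at 6.76 ± 1.24 (SD, n = 3). Among metabolic enzymes, the thioredoxin reductase gene trxr-1 (WBGene00015553) reached 6.47 ± 1.06 and the mitochondrial aconitase gene aco-2 (WBGene00000041) 6.38 ± 2.12. The glycosylation genes sqv-6 and algn-7 stood at 6.87 ± 1.62 and 6.74 ± 1.35, the Ras exchange factor gene sos-1 at 6.33 ± 1.57, and the actin regulator gene wve-1 at 5.95 ± 1.18 (SD, n = 3). Y54E10BR.2 and sumv-2 had 773 and 649 CLIP reads against 3 input reads in all, pooled folds of 162 (95% exact counting interval 55.2 to 787) and 136 (46.3 to 661). Y111B2A.12 and Y92H12BL.1 had log2 ratios of 7.24 ± 1.90 and 6.55 ± 1.67 (SD, n = 3).

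**Figure D1:**
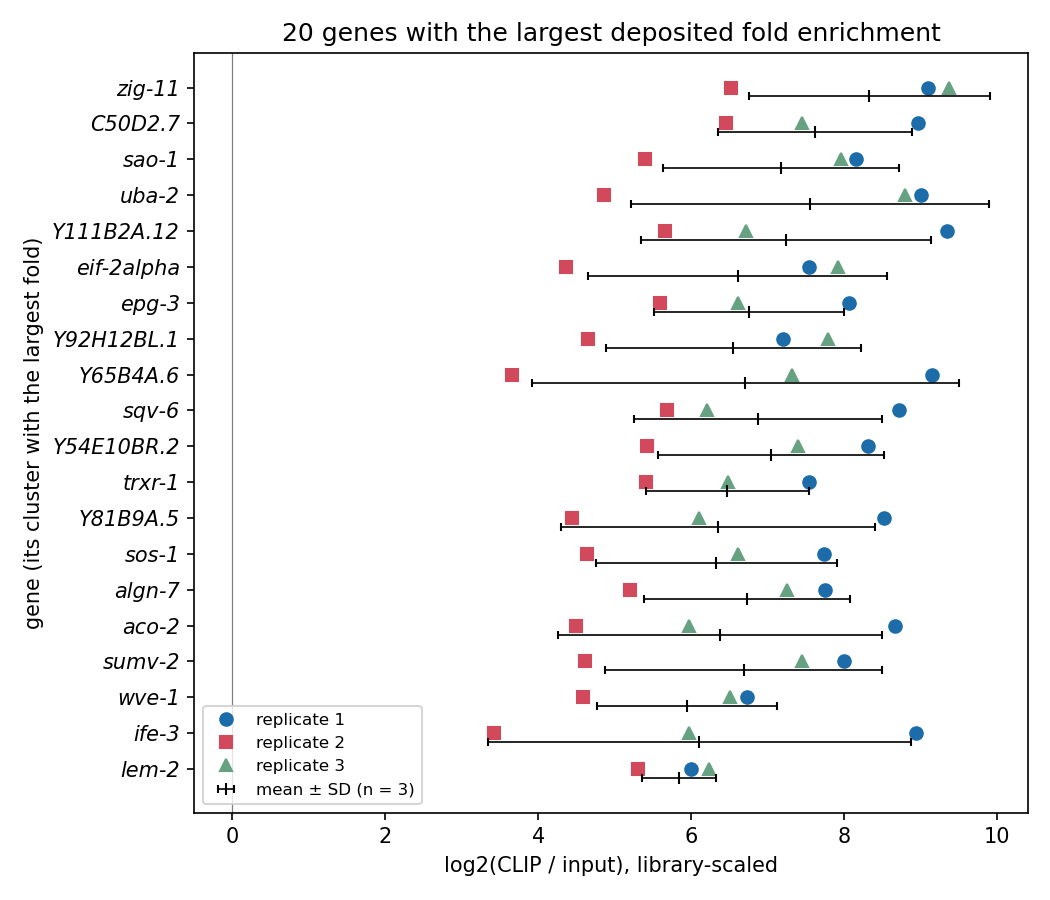
Library-scaled log2 ratio of CLIP over input reads (horizontal axis) for the 20 genes with the largest deposited fold (vertical axis), 1 symbol per replicate, with the mean ± SD of 3 replicates in black. Each gene is shown by its cluster with the largest deposited fold. Every point lies above 0, zig-11 has the highest mean at 8.33, and replicate 2 gives the lowest value for each gene.

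Several genes carried arrays of clusters. spsb-1 (WBGene00021597), which encodes a SPRY and SOCS box protein, had 11 clusters, 5 in its 3' UTR and 6 in introns. C35E7.6 (WBGene00016458, chromosome I) had 7 clusters, all in the 3' UTR between positions 10819137 and 10820552. The cell motility gene unc-34 and the gene Y56A3A.2 also had 7 each, and F58D5.5 and K02F3.2 had 6. Of the 232 genes with a 3' UTR cluster, 106 had 2 or more, and these held 70.8% of the 3' UTR clusters. Neighbouring 3' UTR clusters of a gene were separated by a median of 60 bases over 199 pairs.

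**Figure D2:**
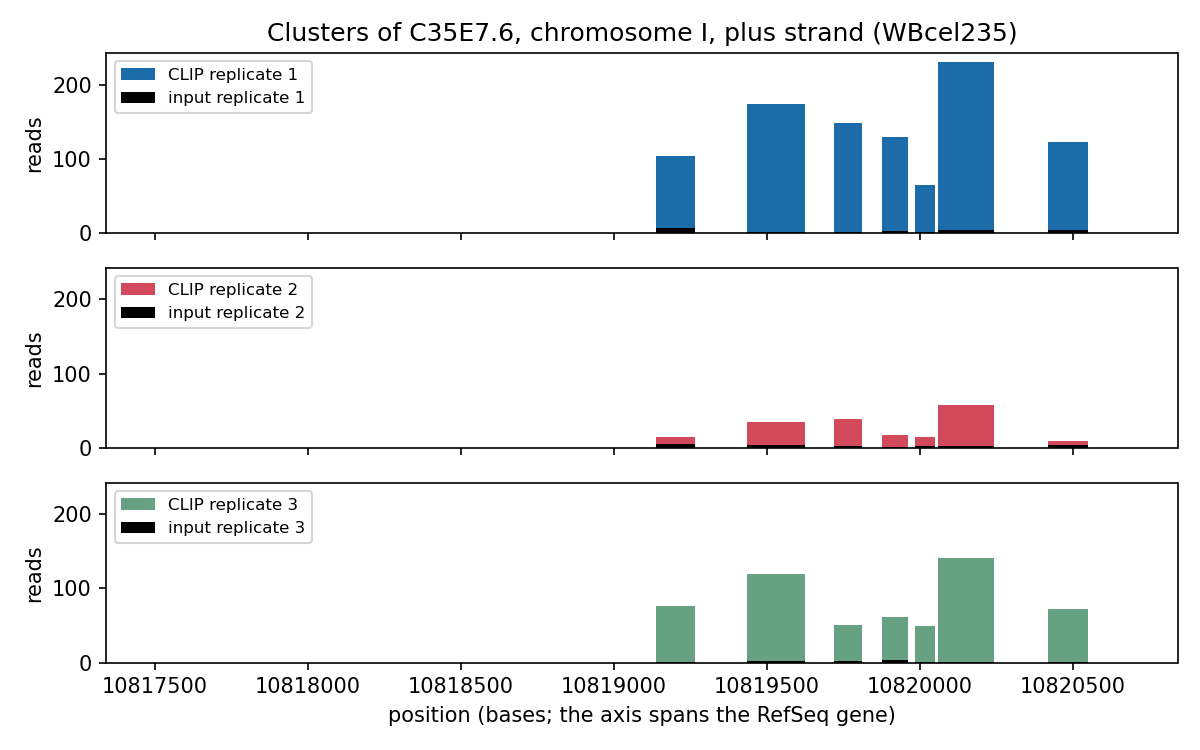
Reads per cluster (vertical axis) along the C35E7.6 gene on chromosome I in WBcel235 (horizontal axis, bases), with 1 panel per replicate, CLIP in colour and input in black drawn over it. The 7 clusters lie in the 3' UTR, and the tallest, from 10820061 to 10820244, had 231, 57 and 141 CLIP reads against 3, 2 and 1 input reads.

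In edgeR's quasi-likelihood test, 389 of the 636 clusters passed the filter on low counts, and 385 of them were higher in CLIP than in input at an adjusted p under 0.05. None was lower, since all 389 fitted folds were above 0, and DESeq2 with the same totals also called 0 lower. The median log2 fold was 4.54, with quartiles of 3.86 and 5.40. With input counts of 1 taken as 0, it was 5.21, with quartiles of 4.11 and 7.44. These clusters had been selected on the same libraries for enrichment, so the count is a description and not independent evidence of binding. The count was 596 without CLIP replicate 2, 605 without input replicate 2 and 629 without the filter or with DESeq2, because more clusters then entered the test. Under TMM scaling, which centres these enriched clusters on 0, the median was -0.02, with 33 clusters higher and 42 lower.

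Replicates differed in strength. In the authors' deposited table, the per-replicate test gave a p-value under 0.05 for 635, 297 and 633 of the 636 clusters in replicates 1, 2 and 3, and for 293 clusters in all 3. The median library-scaled log2 ratio over the 636 clusters was 4.91, 2.10 and 4.29. In replicate 2, 64 of the 636 clusters were deposited as depleted, that is with CLIP not over input, against 0 in replicate 1 and 2 in replicate 3. Not every listed cluster was therefore enriched in all 3 replicates. Across clusters, which are not independent replicates, the ratios of replicates 1 and 3 had a Pearson r of 0.733, against 0.649 for replicates 1 and 2 and 0.554 for replicates 2 and 3.

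Messenger RNA 3' UTRs made up the largest class of clusters. Of the 636, 431 (67.8%) lay in a 3' UTR, 97 (15.3%) in an intron, 58 (9.12%) in a tRNA, 13 in other non-coding RNAs, 11 in snRNAs and 7 in snoRNAs. A further 12 spanned 2 locations of a gene, and only 3 were assigned to exons. Among clusters of protein-coding genes, 431 of 543 (79.4%) were in a 3' UTR, and 232 of 290 protein-coding genes had at least 1 such cluster. Among clusters of protein-coding genes, the share rose to 87.3% for clusters at least 2 times over the lowest deposited fold and to 96.7% (237 of 245) within the 318 clusters with the strongest p-values. Both cuts favour clusters with many CLIP reads. The median 3' UTR cluster had 83, 20 and 48 of these in replicates 1, 2 and 3, against 23, 4 and 21 in introns. The rise may therefore follow read number and is not a measure of stronger binding in 3' UTRs.

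The median library-scaled log2 ratio of 3' UTR clusters was 4.16 ± 1.50 (SD of the 3 replicate medians), that of tRNA clusters 3.56 ± 1.13, that of intron clusters 2.86 ± 1.80 and that of snoRNA clusters 2.48 ± 1.05. Within replicates, 3' UTR clusters exceeded intron clusters by 1.30 ± 0.43 and tRNA clusters by 0.60 ± 0.43 (SD, n = 3), with the same sign in 3 of 3 replicates. Their excess over snRNA clusters was 1.09 ± 1.04 and over other non-coding RNA clusters 0.25 ± 0.72 (SD, n = 3), each positive in 2 of 3 replicates. An exact sign-flip test on 3 replicates cannot go below 0.25. limma's camera test ranked 3' UTR clusters above the other tested clusters with an adjusted p of 9.56e-14 at its preset correlation. This call was lost with an estimated correlation, at an adjusted p of 0.714. It ranked tRNA clusters below the others at an adjusted p of 0.00709, which became an adjusted p of 0.813 with an estimated correlation. It did not separate the 6 tested intron clusters from the others (adjusted p of 0.708). Their edgeR median log2 fold was 4.45, against 4.79 for 3' UTR clusters. Over all clusters, 70 of 97 in introns and 155 of 431 in 3' UTRs had an input count of 1 in all 3 inputs. The ratio of intron clusters thus rests mostly on CLIP reads, and the difference is not a measure of weaker binding.

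**Figure D3:**
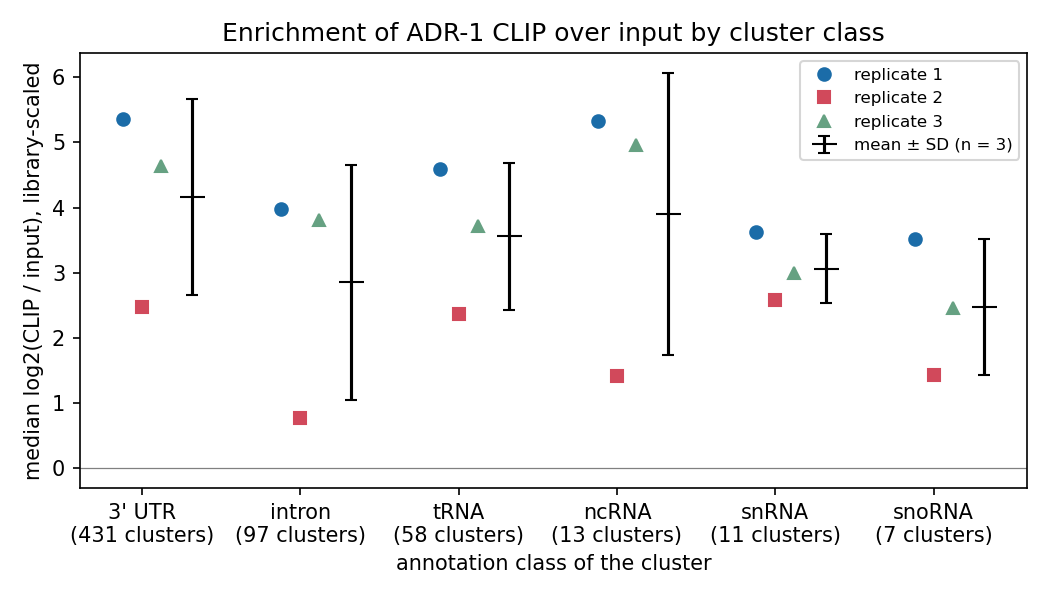
Median library-scaled log2 ratio of CLIP over input reads (vertical axis) per annotation class of cluster (horizontal axis, number of clusters in brackets), 1 symbol per replicate, with the mean ± SD of 3 replicates in black. 3' UTR clusters have a mean of 4.16 and intron clusters of 2.86, and replicate 2 is the lowest in each of the 6 classes plotted.

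The 97 intron clusters lay in 64 genes and had few reads. Besides the 6 in spsb-1, there were 5 in M01H9.3 and 4 in crh-1, which encodes the CREB transcription factor; the latter pair was chosen after the values were seen. The median intron cluster had 23, 4 and 21 CLIP reads, 70 of 97 had an input count of 1 in all 3 inputs, and 5 of 97 reached p under 0.05 in all 3 replicates. Among exon clusters, that of adr-1 itself (WBGene00000079, chromosome I, 7774675 to 7774743) had 15, 13 and 19 CLIP reads against 2, 1 and 2 input reads, a log2 ratio of 2.57 ± 0.20 (SD, n = 3). Its edgeR adjusted p was 4.12e-05, which became 0.0656, 0.0522 and 0.0662 without input replicates 1, 2 and 3, and its log2 fold was -1.86 under TMM scaling. The histone gene his-4 had an exon cluster at 1.58 ± 2.74 (SD, n = 3), a mean within the spread of its replicates. Its edgeR adjusted p of 0.00424 became 0.0850 without CLIP replicate 1, 0.0722 without input replicate 1 and 0.0948 without input replicate 3, and under TMM scaling it was called lower in CLIP, at a log2 fold of -2.47.

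The planned comparison of classes set the 636 clusters against the 100 reproducible clusters outside the uniquely annotated list. A 3' UTR annotation was more frequent in the former, with 431 of 636 against 14 of 100 (Fisher's exact test, two-sided, adjusted p = 3.55e-24). Introns accounted for 97 against 2 (adjusted p = 6.71e-05). The remainder held more tRNA clusters, 40 of 100 against 58 of 636 (adjusted p = 2.82e-13), and more clusters of other non-coding RNAs, 43 against 32 (adjusted p = 1.07e-21). The remainder was classed here with non-coding RNAs first; with 3' UTRs first, 3' UTRs accounted for 437 of 636 against 33 of 100 (odds ratio 4.42 instead of 12.5) and other non-coding RNAs for 32 of 636 against 25 of 100. Of those 100 clusters, 81 had p under 0.05 in 2 or 3 replicates and 19 in 1 replicate, whereas each of the 636 had it in 2 or 3. The remainder thus mixes clusters left without a single annotation and clusters short of that significance. The comparison is not one between bound and unbound RNA. A single annotation was also a condition of the list, and in 58 clusters of the remainder a non-coding RNA lay inside an intron of another gene. In the remainder, an intron was assigned only where no other annotation was present. The class differences thus follow in part from the annotation rule, and their p-values do not measure where ADR-1 binds.

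Of 12 known ADAR substrates listed before the data were examined, 8 had a significant cluster: C35E7.6, lem-2, pop-1, lam-2, unc-64, Y75B8A.8, alh-7 and the non-coding RNA rncs-1. Together they held 25 clusters, 22 of them in 3' UTRs. lem-2, which encodes an inner nuclear membrane protein, reached 5.84 ± 0.48 (SD, n = 3). pop-1, the TCF transcription factor gene of the Wnt pathway, had 5 clusters, and that with the largest deposited fold stood at 5.62 ± 1.19 (SD, n = 3). The laminin gene lam-2 stood at 5.56 ± 1.12 and the syntaxin gene unc-64 at 4.50 ± 1.22. rncs-1, a hairpin RNA known to inhibit Dicer, was lower at 4.14 ± 2.19, Y75B8A.8 at 4.07 ± 1.20 and the aldehyde dehydrogenase gene alh-7 at 3.37 ± 2.41 (SD, n = 3). In all 8 genes, the cluster with the largest deposited fold passed the edgeR test, while rncs-1, Y75B8A.8 and alh-7 fell below a log2 fold of 0 under TMM scaling.

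Of 42 translation factor genes, 8 were bound. The cluster with the largest deposited fold passed the edgeR test in 6 of them and had p under 0.05 in all 3 replicates in 4. Its log2 ratio was as low as 2.57. eif-2alpha (WBGene00021351), the regulated subunit of the initiation factor that brings the initiator tRNA, reached 6.61 ± 1.95, and Y65B4A.6, named eif-4A3 in RefSeq, 6.71 ± 2.79 (SD, n = 3). The cap-binding protein gene ife-3 stood at 6.11 ± 2.76 and eif-3.E at 4.31 ± 2.20, the latter below 0 under TMM scaling. Cytosolic ribosomal protein genes gave 1 of 65, an intron cluster in rpl-3 at 2.94 ± 1.43 (SD, n = 3), also below 0 under TMM scaling and with an edgeR adjusted p of 0.0650 without input replicate 1. The difference between both lists was not tested.

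Germline and oocyte genes gave 6 bound members of 101. The cluster with the largest deposited fold passed the edgeR test in 5 of them and had p under 0.05 in all 3 replicates in 2. The sex determination gene tra-1 had a log2 ratio of 4.52 ± 1.26, the RNA helicase gene cgh-1 3.45 ± 2.36, the helicase gene znfx-1 3.90 ± 1.25 and lin-41 3.02 ± 2.38 (SD, n = 3), with the last 3 below 0 under TMM scaling. The edgeR adjusted p of lin-41 was 0.00263, and 0.0506 without input replicate 1, and lin-41 was called lower in CLIP under TMM scaling. From 59 genes of RNA editing and small RNA machinery, adr-1 and the germline nuclear Argonaute gene hrde-1 were bound, hrde-1 at 5.33 ± 1.04 (SD, n = 3). Among heat shock and proteostasis genes, 4 of 65 were bound: dnj-24 at 6.38 ± 1.32, dnj-20 at 4.39 ± 1.37, the mitochondrial chaperone gene hsp-6 (below 0 under TMM scaling) at 4.22 ± 1.44 and the chaperonin gene cct-8, outside the edgeR filter, at 3.07 ± 1.88 (SD, n = 3).

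No cluster named a vitellogenin (0 of 6), a cuticle collagen (0 of 179), a major sperm protein (0 of 64), a neuropeptide (0 of 152), an intestine gene (0 of 77), a hypodermis gene (0 of 48) or a protein-coding gene of the mitochondrial genome (0 of 12). Muscle structure genes gave 2 of 57, act-4 at 2.42 ± 2.01 and mlc-1 at 3.60 ± 1.67, and synaptic genes 2 of 102, unc-64 and itsn-1, the latter at 2.46 ± 0.73 (SD, n = 3). act-4, mlc-1 and itsn-1 fell below 0 under TMM scaling, act-4 and itsn-1 with a call as lower in CLIP, and the edgeR adjusted p of act-4, 0.0107, became 0.171 without input replicate 1, 0.116 without input replicate 3 and 0.0737 with input counts of 1 taken as 0. Histones gave 1 of 82. Few members of these lists were expected among the bound genes by chance, 2.55 collagens and 0.0871 vitellogenins against all protein-coding genes, too few for a depletion to pass (Fisher's exact test, adjusted p of 0.470 with 0 collagens bound).

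Against genes with only reproducible clusters outside the list, an excess of a gene list could not have passed. That background held members of the synaptic list only, and with all 8 members of known ADAR substrates or of translation factors on the bound side, Fisher's exact test gave a p of 0.114 for each, or 0.911 after adjustment over 16 lists. Against all protein-coding genes, known ADAR substrates had 7 bound members where 0.160 were expected (Fisher's exact test, adjusted p = 6.34e-10), translation factors 8 where 0.610 were expected (adjusted p = 1.10e-06) and germline genes 6 where 1.47 were expected (adjusted p = 0.0190). Heat shock genes, with 4 where 0.929 were expected, did not pass at an adjusted p of 0.0559. That background takes no account of expression in these animals, and a gene with no reads could not have been bound.

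Bound genes lay more often on the arms of autosomes, where the long inverted repeats of the worm genome are known to be frequent. With arms taken as the outer 30% of each end, 207 of 283 bound protein-coding genes (73.1%) were on arms, against 34 of 61 genes (55.7%) with only reproducible clusters outside the list (Fisher's exact test, two-sided, p = 0.00888). Among the other protein-coding genes of the autosomes, 54.3% were on arms (Fisher's exact test, p = 1.61e-10). The 61 genes take in those named by a cluster in their intron, and ptr-13 and twk-13 were named by clusters classed as tRNA. Of the 100 clusters outside the list, 81 had p under 0.05 in 2 or 3 replicates, so the first comparison is not between bound and unbound genes. The second takes no account of expression in these animals. Whether the bound genes lie near inverted repeats was not tested. Strong examples on arms were zig-11, C50D2.7 and ife-3, the last at positions 6779 to 6871 of chromosome V.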

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

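The tests of CLIP totals, of class ratios and of the clusters outside the uniquely annotated list were chosen after the results were seen. The count of splits of the libraries was planned.

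Of the 100 reproducible clusters left out of the uniquely annotated list, 81 had p under 0.05 in 2 or 3 replicates. They were selected for enrichment on the same libraries, so their calls are a description and not independent evidence of binding. Of the 81, edgeR tested 68 and called 61 higher in CLIP than in input; under TMM scaling 5 were higher and 24 lower. Their median pooled fold was 12.9. limma's camera test ranked the 74 tested clusters outside the uniquely annotated list below the other clusters (adjusted p = 6.55e-07, and 0.714 with an estimated correlation). The strongest lay in a 3' UTR shared by Y39A1A.21 and Y39A1A.22 on chromosome III (10702935 to 10703069, minus strand), with 6593 CLIP reads against 7 input reads, a pooled fold of 592 (95% exact counting interval 287 to 1472). This is above the pooled fold of 414 for zig-11, although the counting intervals overlap. A cluster at 2707153 to 2707238 of chromosome III, annotated to both cox-6B and set-27, had a pooled fold of 152 (69.5 to 414), and another at 2707560 to 2707656 had 149 (50.7 to 723). With non-coding RNAs taken first, 38 of the 81 clusters were classed as tRNA, 37 as other non-coding RNA and 6 as 3' UTR. A cluster that overlapped both a non-coding RNA and a 3' UTR is counted under the former. In 58, a non-coding RNA lay inside an intron of another gene. These genes were chosen after their values were seen.

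CLIP replicate 2 gave weaker enrichment than the others, with a median scaled log2 ratio of 2.10 against 4.91 and 4.29. A single lower depth of that library would reduce all clusters alike, and the ratio of replicate 2 to replicate 1 reads was 0.0984 for the median tRNA cluster and 0.218 for the median 3' UTR cluster, a quotient of 0.452 (95% interval over resampled clusters 0.410 to 0.493). As the same quotient was 0.527 (0.448 to 0.596) for replicate 3 over replicate 1, and the interval holds no spread between libraries, this test does not decide on the depth of replicate 2. A shared CLIP total also remains open: the totals behind the deposited statistics were equal, at 0.999846 ± 0.000974 (standard error) for replicate 3 over replicate 1, which could come from reads drawn to equal depth or from 1 total used for every replicate, and the tables hold no other measure of depth. With CLIP totals set by the median cluster, 564 clusters were higher in CLIP, at a median log2 fold of 4.86, and no biological explanation was tested.

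Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave 385 clusters past the threshold, and the highest of the other splits gave 0. With 10 splits, a share under 0.05 cannot be reached. The clusters had also been selected for CLIP over input in these same libraries, which favoured the real split in advance. No conclusion is drawn from the count.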

How the results depend on the processing

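The scaling by recovered totals, the DESeq2 test with these totals, the totals set by the median cluster, the 2 settings for input counts of 1 and the camera test with an estimated correlation were chosen after the data were seen; the others were planned. The count of 385 clusters higher in CLIP fell to 33 under TMM scaling and 30 with DESeq2 size factors, with 42 lower in both, and the median log2 fold of 4.54 became -0.024 and -0.10; both scalings centre the listed clusters on 0 by construction. The count was 629 without the filter and 629 with DESeq2's test (all 636 tested), 125 among the 130 clusters tested with input above 1 in all libraries, and 373 with input counts of 1 taken as 0, where the median log2 fold was 5.21. Leaving out a library gave 342 to 605 clusters, the lowest without CLIP replicate 1, and 596 without CLIP replicate 2, 605 without input replicate 2. With the replicate block, the pairing by lysate gave 385 clusters, all 385 shared, and it changed no call of a cluster class. The 6 camera calls of cluster classes were lost with an estimated correlation (adjusted p of 0.714 to 0.813).

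The 318 clusters with the strongest p-values named 148 of the 315 genes, and the 3' UTR share of protein-coding clusters of 79.4% became 96.7% there and 87.3% for clusters 2 times over the lowest fold. All 636 clusters overlapped the reproducible list under each overlap rule. In Fisher's exact tests, class differences and the arms kept their direction and side of the threshold under every alternative run for them, with p of 0.000456 to 0.0151 for the arms, and 1.61e-10 against all protein-coding genes. The class differences follow in part from the annotation rule that divides the lists. Against all protein-coding genes, known ADAR substrates (6.34e-10), translation factors (1.10e-06) and germline genes (0.0190) passed, while histones (adjusted p of 1) and synaptic genes (0.962) changed direction without passing. The matched permutation, limited by the same background, passed no list (adjusted p of 1 for every list).

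Of the 47 named genes with a fit, 15 fell below a log2 fold of 0 under TMM scaling and 18 with DESeq2 size factors, the cause being the centring; under each, 19 kept their call as higher and 4 (his-4, act-4, itsn-1, lin-41) were called lower. Under TMM these were Y56A3A.2 -0.32, rncs-1 -0.16, Y75B8A.8 -0.28, alh-7 -1.17, adr-1 -1.86, rpl-3 -1.81, eif-3.E -0.12, his-4 -2.47, itsn-1 -2.08, mlc-1 -0.86, act-4 -2.23, cgh-1 -1.03, znfx-1 -0.50, lin-41 -1.54 and hsp-6 -0.30. With size factors they were Y56A3A.2 -0.40, rncs-1 -0.23, unc-64 -0.012, Y75B8A.8 -0.37, alh-7 -1.24, adr-1 -1.94, rpl-3 -1.89, eif-3.E -0.20, his-4 -2.54, itsn-1 -2.16, mlc-1 -0.93, act-4 -2.30, tra-1 -0.044, cgh-1 -1.10, znfx-1 -0.58, lin-41 -1.61, dnj-20 -0.051 and hsp-6 -0.37. Inverted repeats and folding energy, with their alternatives, were not run because no genome sequence was used here. Input depth limits the fold of many clusters: the median cluster had 1 input read per library.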

Other observations

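All tests in this part were chosen after the results were seen. Bound protein-coding genes were unevenly spread over chromosomes when set against all protein-coding genes. That background takes no account of expression in these animals, and a gene with no reads could not have been bound. The p-values therefore do not separate uneven binding from uneven expression. Chromosome III held 87 of 290 (30.0%) where 38.3 were expected from all protein-coding genes (Fisher's exact test, adjusted over 6 chromosomes, p = 3.65e-13), and chromosome I held 77 where 41.8 were expected (adjusted p = 9.24e-08). Chromosome V held 41 where 72.5 were expected (adjusted p = 1.17e-05), chromosome IV 33 where 47.6 were expected (adjusted p = 0.0243) and chromosome X 7 where 39.6 were expected (adjusted p = 1.17e-10). Chromosome II, with 45 where 50.0 were expected, did not pass (adjusted p = 0.481). The genes lam-2, act-4 and mlc-1 are among the 7 on X.

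The low share on X (2.41%, 95% exact interval 0.976 to 4.91) stayed under the 13.7% of all protein-coding genes when left-out clusters were added. With every protein-coding gene named by a reproducible cluster, 19 of 363 were on X (5.23%, 3.18 to 8.05). Of these 363, 290 were the bound genes themselves, so the 2 shares are not independent. The added genes include ajm-1 and deg-1 on X, named by clusters classed as tRNA. Among genes of reproducible mRNA clusters, 8 of 303 were on X (2.64%, 1.15 to 5.14). A candidate explanation is that bound RNAs come largely from the germline, whose genes are known to be rare on X: of the 101 genes of the germline and oocyte list, 2.97% (0.617 to 8.44) lie on X. As only 6 of these 101 genes were themselves bound, this remains a hypothesis. On chromosomes III and IV, bound genes differed from that list: 30.0% against 16.8% on III, and 11.4% against 21.8% on IV (Fisher's exact test, adjusted p = 0.0378 for each). A written list of 101 genes need not share the chromosomal spread of all germline genes. The comparison therefore cannot decide whether germline origin accounts for III and IV.

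On chromosome X, the non-coding RNA tts-1 had clusters with log2 ratios of 4.84 ± 1.72 and 4.44 ± 1.80 (SD, n = 3), and rncs-1, Y81B9A.5 and R106.8 had 3, 2 and 2 clusters. The mitochondrial small ribosomal RNA (WBGene00014454, MtDNA, 957 to 1113) held 14.2%, 24.7% and 23.5% of the CLIP reads in clusters of replicates 1, 2 and 3 and 40.0%, 19.4% and 45.7% of the input reads, at a log2 ratio of 2.60 ± 0.35 (SD, n = 3).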
